A study of Drosophila melanogaster with 8 samples.

How the data were processed

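All 8 arrays were used, 4 for each comparison, and each array was assigned to its comparison, replicate and dyes from its title and channel labels. Per the labels, 100 ng of total RNA of each pool was amplified over 2 rounds and 20 µg of labelled RNA with 700 pmol of dye was hybridised. The spot intensities, per the file headers, were foreground and local background values from the scanner software in RFU for both dyes, with a mark on bad spots (6 to 112 per array). The log2 ratios of the value table, as deposited, were normalised by the authors, and limma is the tool listed for their processing (version not given in the sources used here). Those log2 ratios were centred near 0 per array, with medians of -0.003, -0.00195, 0.0054 and -0.0013 for heart against aorta and -0.0153, -0.0175, -0.0034 and -0.00645 for dorsal vessel against whole larva, and 246 to 352 spots per array were empty, the marked ones among them. They gave aorta over heart and dorsal vessel over whole larva, and their correlation with log2 Cy5 over Cy3 of the uncorrected intensities was 0.923 to 0.989 in absolute value.

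Each array held 15744 spots, of which 14636 carried gene oligonucleotides, 264 external controls and 260 negative controls, and 584 were empty. Of 14456 oligonucleotides with a gene, 12644 were named through the locus tag, 1139 through an older identifier and 673 kept the name in the files. They covered 13303 genes, 881 of them with more than 1 oligonucleotide. Probes were not realigned; the files cite annotation releases 4.1 and 4.2, and only gene names were taken from the current reference.

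RFU values were scaled by a common factor of 36.9 to a 16-bit range before normexp background correction with an offset of 50, which is 1.35 RFU. The offset had been planned without knowing the unit of the files, and a literal offset of 50 RFU was tried beside it. Each array was then normalised by loess (span 0.3, 4 iterations) with controls and marked spots at weight 0. Replicate spots were averaged, and the brightest oligonucleotide stood for a gene. A gene was tested where it lay above the 95th percentile of negative and empty spots on at least 2 of the 4 arrays in at least 1 of the RNAs of a comparison. Medians of lists cover all tested members, while the list test took only members with values on all arrays.

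All 8 arrays were fitted together in limma with 3 coefficients, 1 for each comparison and 1 for the dye. The dye effect was taken as shared by all 8 arrays, but those of the 2 sets of 4 arrays correlated across genes at rho = 0.0598. Pairing was kept by the ratio within an array. P values came from moderated t tests, adjusted by Benjamini and Hochberg over all tested genes of a comparison, with a threshold of 0.05. Residual degrees of freedom were 5, with prior degrees of freedom of 2.27 and 2.33. Of the genes that passed, the smallest fold was 1.37 for heart against aorta and 1.19 for dorsal vessel against whole larva, and 82 and 1012 differed at least 2-fold. Before adjustment, 1211 and 3387 genes had p below 0.05. Of the genes that passed, 13 and 218 had several oligonucleotides, and for 5 and 85 of these another one had the opposite sign.

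The 27 gene lists were written from general knowledge before any value was seen, and 24 had at least 4 measured members in each comparison. They were tested with limma's camera at a preset correlation between genes of 0.01, with camera at a correlation estimated for each list, and with limma's rotation test fry. By camera 11 lists passed for heart against aorta (9 up, 2 down) and 14 for dorsal vessel against whole larva (5 up, 9 down). With the estimated correlation 0 passed in either, and by fry 2 and 15. The estimate comes from 8 arrays and 5 residual degrees of freedom. Genes were named by a rule set in advance: the 10 largest differences in each direction among those past the test with the same sign on every array, up to 4 members of each list, taken by the smallest adjusted p, and a fixed set of cardiac, Hox and marker genes such as abd-A, tin, Hand, Ih, Mhc, Hml and Lsp2, whatever their result; genes known only by a number were not described. Where a gene was detected in only 1 of the RNAs, its fold is given as at least the value measured. That value is an estimate and holds no margin for its error. List medians used the same values, so they are no separate check.

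The steps were tested on simulated arrays with known answers. Of genes changed 1.5-fold, 2-fold and 4-fold, 25.0, 67.7 and 87.7% were found for heart against aorta and 25.8, 55.2 and 90.9% for dorsal vessel against whole larva, all with the right sign. Unchanged genes made up 11.4 and 10.2% of the calls, above the 5% intended, and 2.17 and 7.41% when only the 4 arrays of a comparison were fitted. With no gene changed, 2 and 0 genes and 0 lists passed. A shift put into the sarcomere list was found in that list alone. Noise was simulated independently for each gene, so these list results cannot show how the list test behaves where members vary together. The only dye effect simulated was a trend with signal, the same on all arrays. The shares of unchanged genes therefore do not cover dye effects of single oligonucleotides that differ between the sets of arrays. Ratios were compressed for dim genes: the median ratio of estimated to true log2 was 0.167 under 2 RFU over background, 0.378 from 2 to 10, 0.790 from 10 to 50 and 0.951 above for heart against aorta, and 0.172, 0.405, 0.728 and 0.915 for dorsal vessel against whole larva.

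Analyses used R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The labels call the replicates biological, so each array counted as 1 replicate. Some genes written into the lists, such as Amy-p and Hsp22, were not found by name among the arrays' oligonucleotides and were not analysed here.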

Results

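The dorsal vessel is the circulatory organ of the fruit fly larva, a tube under the dorsal midline with a contractile posterior heart and a narrower anterior aorta. RNA abundance was measured in L3 larvae of Drosophila melanogaster kept at 25 °C, on 8 oligonucleotide arrays that each carried 2 dye-labelled RNAs. On 4 arrays the heart was compared with the aorta, separated at the cardiovascular valve, with 10 individuals in each pool. On the other 4 arrays the whole dorsal vessel was compared with sibling whole larvae, with 5 individuals in each pool. Each comparison had 4 biological replicates. Replicates 1 and 2 carried aorta or dorsal vessel in Cy3, and replicates 3 and 4 carried them in Cy5.

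Signals were low. The median gene spot lay between 1.22 and 2.48 fluorescence units (RFU) per channel, over local backgrounds of 0.945 to 2.08 RFU, and between 25.0 and 51.1% of the oligonucleotides with a gene rose above the detection level of a channel. Across genes, the log2 ratios of dorsal vessel over whole larva correlated between replicates at r = 0.791 to 0.890. The log2 ratios of heart over aorta correlated at r = 0.484 between replicates 1 and 2 and at r = 0.474 between replicates 3 and 4, the pairs of the same dye orientation. Between opposite orientations they correlated at r = 0.0214 (replicates 1 and 4), 0.0982 (2 and 3), 0.170 (2 and 4) and -0.477 (1 and 3; Spearman rho = -0.176). Replicates 1 and 3 also had large opposite shifts of genes of the midgut, salivary glands and testis, described below. Log2 ratios of genes near background understate the change.

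Heart and aorta differed in a neuropeptide, in hemocyte and matrix genes and in a posterior Hox gene. Log2 ratios are given as heart over aorta, opposite in sign to the deposited value table, with the standard error of the fit (n = 4 arrays for each value unless another n is given). Of 5780 genes tested, 109 were higher in heart and 43 were higher in aorta, 152 in all (2.63%), at an adjusted p below 0.05 in limma, and 149 of them had the same sign on all 4 arrays. The largest difference was that of Ms, the gene of the neuropeptide myosuppressin, 25.3-fold higher in heart (log2 ratio 4.66, SE 0.64, adjusted p = 0.0165). Its size was not stable, with a log2 ratio of 1.62 to 5.72 over the alternatives of processing and arrays. Also higher in heart were wun2, of a lipid phosphate phosphatase (2.94, SE 0.26, adjusted p = 0.00392), the carbonic anhydrase gene CAH7 (2.73, SE 0.29, adjusted p = 0.00794), sosie (2.73, SE 0.20, adjusted p = 0.00276) and Agps, of ether lipid synthesis (2.07, SE 0.25, adjusted p = 0.0108). Higher in aorta were Lapsyn, of a leucine-rich repeat protein of synapses (-2.01, SE 0.19, adjusted p = 0.00536), the potassium channel gene sand (-1.84, SE 0.16, adjusted p = 0.0038) and Dh44-R2, of a receptor of diuretic hormone (-1.28, SE 0.15, adjusted p = 0.00995). Ms missed the test without replicate 1, 2 or 4 (adjusted p = 0.0511, 0.0717 and 0.0576), and Agps missed it without replicate 2 (adjusted p = 0.0556). With median centring in place of loess, sand and Dh44-R2 missed it (adjusted p = 0.0810 and 0.106).

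**Figure D1:**
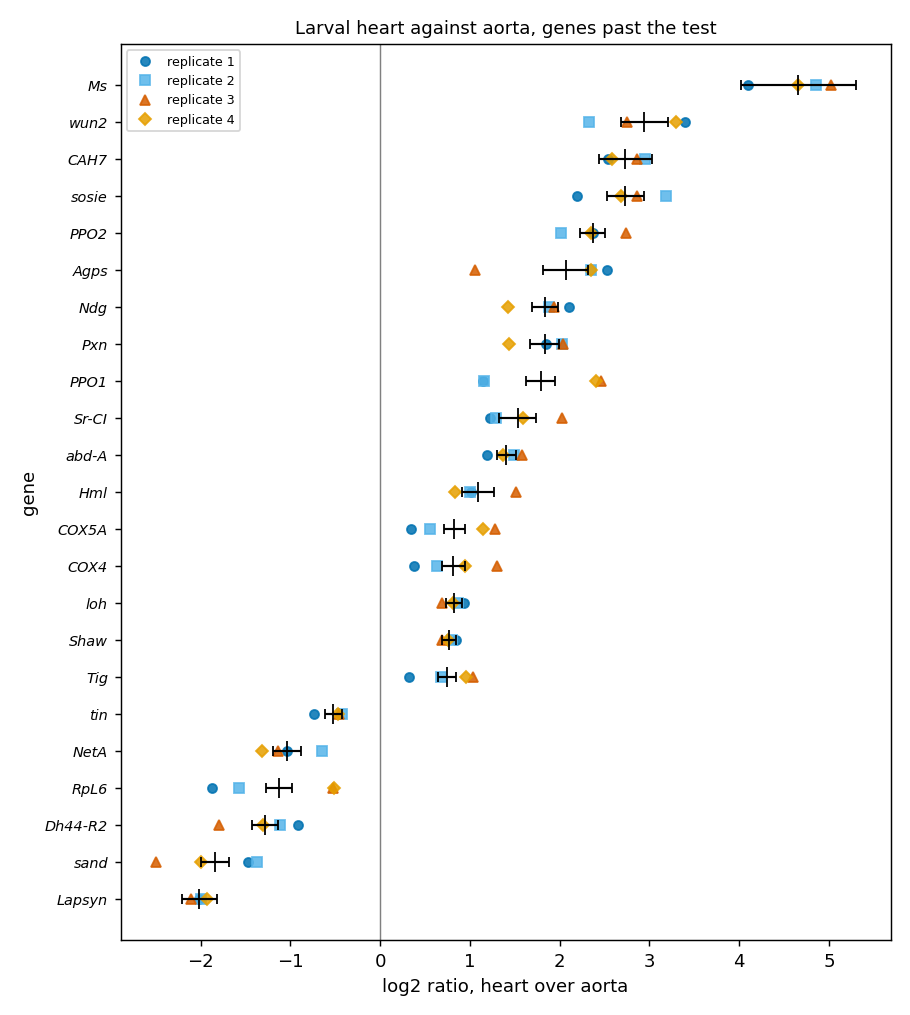
Genes that differed between heart and aorta. Each point is the log2 ratio of heart over aorta on an array, with replicates shown by colour (n = 4 arrays); the black tick is the fitted log2 ratio and the bar its standard error. Positive values mean higher in heart.

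The regional identity gene abd-A was 2.65-fold higher in heart (1.41, SE 0.10, adjusted p = 0.00276). Of 3 Hox genes tested, 1 was higher in heart, 0 were higher in aorta and 2 did not pass, and the same 1 passed when adjusted over the list alone. Abd-B (0.13, adjusted p = 0.527) and Scr (0.02, adjusted p = 0.954) were above detection in heart on 2 arrays and in aorta on 0. Antp and Ubx were not tested: Antp was above detection on 1 array in each RNA, and Ubx on 0. The median of the 3 was 0.13, too few members for a list test.

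Among 12 cardiac transcription factors, tin was higher in aorta, at least 1.43-fold as measured, because it was above detection in heart on 0 arrays (log2 ratio -0.52, SE 0.09, adjusted p = 0.0368). Over the alternatives of processing and arrays, the log2 ratio of tin ran from -0.94 to -0.05. It was the only 1 of the 12 to pass, with 0 higher in heart and 11 not past the test; adjusted over the list alone, 1 was higher in heart and 2 in aorta. The cardiac genes pnr (-0.71, adjusted p = 0.0913), mid (-0.58, adjusted p = 0.235), H15 (-0.51, adjusted p = 0.181), Hand (-0.23, adjusted p = 0.752), svp (-0.23, adjusted p = 0.666) and how (1.04, adjusted p = 0.0925) did not pass, though pnr did without replicate 3 (-0.97, adjusted p = 0.0327). The list median was -0.23 (camera adjusted p = 0.277). The call on tin did not stand on any 3 arrays (adjusted p = 0.152, 0.130, 0.0829 and 0.107 without replicates 1 to 4). Without replicate 2 the list median was -0.41 and the list passed (camera adjusted p = 0.0301).

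Some genes of the basement membrane and matrix were higher in heart. Of 17 tested, 7 were higher in heart, 0 in aorta and 10 did not pass; adjusted over the list alone, 10 were higher in heart. The pericardin gene prc was above detection on 0 arrays in either comparison. Ndg, of nidogen (1.84, SE 0.14, adjusted p = 0.00276), Pxn, of peroxidasin (1.83, SE 0.16, adjusted p = 0.0038), loh, of lonely heart (0.82, SE 0.09, adjusted p = 0.00961) and Tig, of tiggrin (0.75, SE 0.10, adjusted p = 0.0168), were among them. As a group, the list had a median of 0.44 (camera adjusted p = 2.55e-06; adjusted p = 0.406 with an estimated correlation). Singly, loh missed the test without replicate 1 or 2 (adjusted p = 0.0502 and 0.0610), and Tig without replicate 2, 3 or 4 (adjusted p = 0.0922, 0.0541 and 0.0594).

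Several markers of the lymph gland and hemocytes were higher in heart. Of 16 tested, 6 were higher in heart, 0 in aorta and 10 did not pass; adjusted over the list alone, 8 were higher in heart. The prophenoloxidase genes PPO2 (2.37, SE 0.13, adjusted p = 0.00187, 5.16-fold) and PPO1 (1.79, SE 0.16, adjusted p = 0.00425), the scavenger receptor gene Sr-CI (1.53, SE 0.20, adjusted p = 0.0155) and the hemolectin gene Hml (1.09, SE 0.18, adjusted p = 0.0289) were higher in heart; Pxn belongs to this list as well as to the matrix list. The median over the list was 0.71, or 1.63-fold, with 14 of 16 members positive (camera adjusted p = 3.29e-08; adjusted p = 0.406 with an estimated correlation). The replicate medians were 0.58, 0.61, 1.26 and 0.51. The matrix and hemocyte lists were also the 2 that passed a rotation test (fry adjusted p = 0.00512 and 0.00468). Sr-CI missed the test without replicate 2 or 4 (adjusted p = 0.0620 and 0.0576), and Hml on any 3 arrays (adjusted p = 0.0581 to 0.113).

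The sarcomere list passed camera toward the heart, with no single gene past the test and not by fry (adjusted p = 0.184). Of 23 tested, 0 were higher in heart, 0 in aorta and 23 did not pass; adjusted over the list alone, 5 were higher in heart. Zasp52 (0.99, SE 0.21, adjusted p = 0.0599), Zasp66 (0.71, adjusted p = 0.0572) and wupA (0.73, adjusted p = 0.067) lay on the heart side, as did Mhc (0.82, adjusted p = 0.206), while Act57B lay on the other (-0.26, adjusted p = 0.722). The members had a median of 0.45, with 17 of 23 positive (camera adjusted p = 0.000423; adjusted p = 0.582 with an estimated correlation). The replicate medians were -0.05, 0.38, 0.89 and 0.24, and without replicate 4 Zasp52 passed (1.27, adjusted p = 0.0375).

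The list of oxidative phosphorylation passed camera toward the heart, but not fry (adjusted p = 0.387). Of 30 genes of oxidative phosphorylation tested, 3 were higher in heart, 0 in aorta and 27 did not pass (5 higher in heart adjusted over the list alone): COX5A (0.83, SE 0.12, adjusted p = 0.0205), COX4 (0.82, SE 0.13, adjusted p = 0.0266) and COX7A (0.72, SE 0.14, adjusted p = 0.0473). The list median was 0.26 (camera adjusted p = 0.000497; adjusted p = 0.806 with an estimated correlation). The replicate medians were -0.50, 0.08, 0.82 and 0.81, and without replicate 4 the list median was 0.10 and the list did not pass (camera adjusted p = 0.120). Singly, COX4 passed on no 3 arrays (adjusted p = 0.0594 to 0.131), and COX5A and COX7A missed the test without replicate 2 (adjusted p = 0.0869 and 0.197), 3 (0.0573 and 0.102) or 4 (0.0716 and 0.134).

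The lists of glycolysis and the tricarboxylic acid cycle passed camera toward the heart, but not fry (adjusted p = 0.227 and 0.184), with no single gene past the test and negative medians on replicate 1 (-0.17 and -0.13). Of 11 glycolysis genes tested, 11 did not pass (3 higher in heart adjusted over the list alone), among them Ldh (1.49, adjusted p = 0.0759) and Pfk (0.48, adjusted p = 0.0836), with a median of 0.38 (camera adjusted p = 0.0137; adjusted p = 0.736 with an estimated correlation). Of 9 genes of the cycle tested, 9 did not pass (1 higher in heart adjusted over the list alone), among them mAcon1 (0.69, adjusted p = 0.0573), with a median of 0.24 (camera adjusted p = 0.0439; adjusted p = 0.582 with an estimated correlation). Both lists missed the test without replicate 2 (camera adjusted p = 0.0546 and 0.125), 3 (0.0926 and 0.0697) or 4 (0.0756 and 0.185), and the cycle missed it with a block of spots found out of place left out (0.0512). Ldh passed without replicate 1 (2.00, adjusted p = 0.0261).

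Of 18 genes of ion channels and calcium handling tested, 1 was higher in heart, 0 in aorta and 17 did not pass; adjusted over the list alone, 3 were higher in heart and 2 in aorta. The potassium channel gene Shaw was the 1 that passed (0.77, SE 0.08, adjusted p = 0.0064). Sh (0.46, adjusted p = 0.0917), Ndae1 (0.33, adjusted p = 0.274), the pacemaker channel gene Ih (0.07, SE 0.21, n = 3 arrays, adjusted p = 0.897) and the sodium pump gene Atpalpha (-0.41, adjusted p = 0.0773) did not pass, and Ork1 was above detection on 0 arrays. Across the list the median was 0.29 (camera adjusted p = 0.0439; adjusted p = 0.630 with an estimated correlation). The list missed the test without replicate 1 or 2 (camera adjusted p = 0.0665 and 0.257) or with a block of spots found out of place left out (0.0722), and Shaw missed it on the 4 arrays of this comparison alone (adjusted p = 0.0729).

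The lists of cytoplasmic ribosomal proteins and of the cell cycle passed camera toward the aorta, but not fry (adjusted p = 0.184 and 0.137). Of 87 cytoplasmic ribosomal protein genes tested, 0 were higher in heart, 1 in aorta and 86 did not pass, but adjusted over the list alone 24 were higher in aorta, and 82 of 87 were negative. RpL6 passed (-1.12, SE 0.15, adjusted p = 0.0139), though not without replicate 1 or 2 (adjusted p = 0.0566 and 0.0637). As a group, the list had a median of -0.44 (camera adjusted p = 2.70e-14; adjusted p = 0.582 with an estimated correlation), with replicate medians of -0.56, -0.63, -0.07 and -0.31. All 11 cell cycle genes tested were negative, with a median of -0.72, or 1.64-fold: PCNA (-1.41, adjusted p = 0.0856), Cdk1 (-1.02, adjusted p = 0.129), Mcm3 (-0.92, adjusted p = 0.105) and stg (-0.72, adjusted p = 0.115). None of the 11 passed over all genes, and 6 were higher in aorta adjusted over the list alone (camera adjusted p = 0.000134; adjusted p = 0.582 with an estimated correlation). The replicate medians were -0.53, -1.40, -0.14 and -0.38.

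The guidance gene NetA was higher in aorta, 2.05-fold (-1.03, SE 0.16, adjusted p = 0.0255). It was the only 1 of 17 genes of cell adhesion and guidance to pass, with 0 higher in heart, 16 not past the test and the same 1 adjusted over the list alone; mew, of an integrin, did not pass (-0.63, adjusted p = 0.117). The median over the list was 0.01 with a mean of -0.02 (camera adjusted p = 0.856). NetA missed the test without replicate 1, 3 or 4 (adjusted p = 0.0835, 0.0604 and 0.0770). Of 10 signalling genes tested, 10 did not pass, over all genes or over the list alone, among them wg (-0.40, adjusted p = 0.0856) and spi (-0.48, adjusted p = 0.125), with a median of 0.08 (camera adjusted p = 0.999). The 1 receptor of cardioactive peptides tested did not pass (0.16).

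In the lists of nephrocytes, ring gland, fat body, trachea, nervous system and imaginal discs no single gene passed over all genes. Of 7 genes of pericardial cells and nephrocytes tested, 7 did not pass (1 higher in heart adjusted over the list alone), among them pyd (0.41, adjusted p = 0.0721) and Cubn (0.69, adjusted p = 0.146), with a median of 0.19 (camera adjusted p = 0.437). Of 5 ring gland genes, 5 did not pass (median 0.04, camera adjusted p = 0.646), and phtm of this list was above detection on 0 arrays. Of 15 fat body genes, 15 did not pass (3 higher in heart adjusted over the list alone), among them Lsd-1 (0.77, adjusted p = 0.0534) and Lsp2 (-0.50, adjusted p = 0.411), with a median of -0.04 against an upward sign in camera (adjusted p = 0.948). Of 5 genes of the trachea, 5 did not pass, among them pio (0.40, adjusted p = 0.218), but the list did (median 0.25, camera adjusted p = 0.0439; adjusted p = 0.582 with an estimated correlation), and not without replicate 3 (camera adjusted p = 0.0520). Lsd-1 passed without replicate 3 (0.92, adjusted p = 0.0468). The nervous system (5 tested, 5 not past, median -0.10, camera adjusted p = 0.948) and imaginal discs (5 tested, 5 not past, median -0.06, camera adjusted p = 0.680) did not pass.

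Genes of the gut, salivary glands, testis and cuticle varied between replicates more than any group named above. Of 20 midgut genes, 20 did not pass, with replicate medians of 3.56, 0.58, -3.89 and -1.09 (overall -0.31, camera adjusted p = 0.360); betaTry of this list had a log2 ratio of -1.64 with an SD of 5.72. Of 10 genes of the salivary glands, 10 did not pass, with replicate medians of 2.70, 1.86, -2.77 and 0.05 (overall 0.48, camera adjusted p = 0.360), and of 10 genes of the testis and germ line, 10 did not pass, with 3.14, -0.49, -2.53 and 0.05 (overall 0.05, camera adjusted p = 0.947). The 3 genes of the Malpighian tubules tested did not pass (replicate medians 0.39, 1.46, -3.60 and -0.10; overall -0.56). Of 7 genes of epidermis and cuticle, 7 did not pass (2 higher in heart adjusted over the list alone), among them Lcp4 (1.99, adjusted p = 0.0571) and Lcp1 (2.40, adjusted p = 0.0939), but the list did (median 1.44, camera adjusted p = 0.0439; adjusted p = 0.582 with an estimated correlation), and not without replicate 1 (camera adjusted p = 0.138) or with the block of spots found out of place left out (0.0512), while Lcp4 passed without replicate 3 (1.31, adjusted p = 0.0195). Without replicate 1 the midgut list passed at -1.34 (camera adjusted p = 3.18e-06) and the testis list turned to -0.82 (camera adjusted p = 0.0110), and without replicate 3 the salivary gland list passed at 1.42 (camera adjusted p = 6.73e-05).

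**Figure D2:**
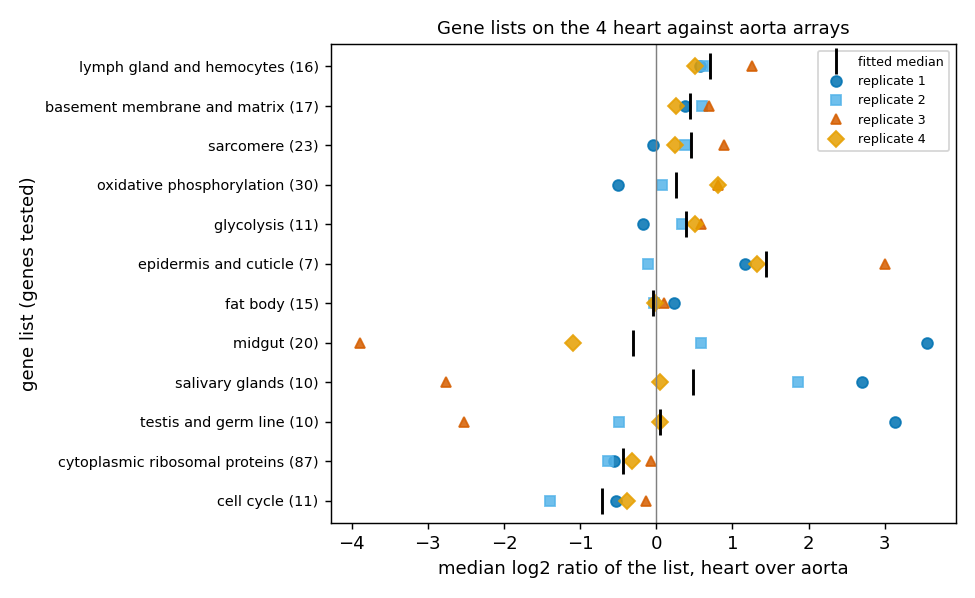
Gene lists between heart and aorta. Each point is the median log2 ratio of heart over aorta of the tested members of a list on an array, with replicates shown by colour (n = 4 arrays). Positive values mean higher in heart.

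The number of genes that differed between heart and aorta depended on single arrays and on the shared fit. Without replicate 1, 2, 3 or 4 the 152 genes became 51, 36, 119 and 69, and without replicate 3 they were 62 higher in heart and 57 higher in aorta. The balance of directions also moved with the processing, to 88 and 9 with median centring and to 230 and 227 with a separate dye effect for each comparison, chosen after the data were seen, so the excess toward heart is not a stable result. A fit of the 4 arrays of this comparison alone found 8. Without replicates 1 and 3, a choice made after their opposite shifts were seen, 24 genes passed, 19 of them among the 152. PPO2 was the only gene named here that passed under all 23 alternatives, and the matrix, hemocyte, sarcomere, ribosomal and cell cycle lists kept their calls under the same 23 at the preset correlation. With the signs of 1 or more arrays turned, camera at that correlation still called 5 to 12 lists. The count of 11 lists therefore does not set the real signs apart. The root mean square residual SD was 0.554 on these arrays and 0.391 on the 4 others, but the median residual SD was 0.222 and 0.253, so genes of large spread varied more on these arrays and the typical gene did not.

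Calls on single genes between heart and aorta also changed with the processing. Of the named genes, Ms, CAH7, PPO1, PPO2 and Lapsyn passed on the 4 arrays of this comparison alone with a dye effect, and the others that passed in the joint fit did not (adjusted p = 0.0570 to 0.0867). With no dye effect on these arrays wun2, sosie, abd-A, Ndg and Pxn passed and PPO1 did not (adjusted p = 0.144). Median centring ended the calls on Tig, COX5A, COX7A, RpL6, NetA and tin as well (adjusted p = 0.0735 to 0.311), and print-tip loess those on tin, COX5A and COX7A (adjusted p = 0.0533, 0.143 and 0.0960). An offset of 50 RFU, chosen after the data were seen, ended those on CAH7, sosie, PPO1, Sr-CI and Hml among others (adjusted p = 0.0536 to 0.0949). Without replicates 1 and 3, CAH7, Lapsyn, Dh44-R2, Shaw, loh and Ms were among those that missed it (adjusted p = 0.0530, 0.0532, 0.0663, 0.108, 0.105 and 0.0927). Of the lists, ion channels, tricarboxylic acid cycle, trachea and epidermis missed camera with median centring (adjusted p = 0.159, 0.0594, 0.159 and 0.0594). With the block of spots found out of place left out, 8 lists passed in place of 11.

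Dorsal vessel and whole larva differed far more widely. Log2 ratios are given as dorsal vessel over whole larva. Of 6820 genes tested, 975 were higher in dorsal vessel and 1505 were lower, 2480 in all (36.4%), and 2363 had the same sign on all 4 arrays. The cardiac gene Hand had the largest enrichment, 47.2-fold (5.56, SE 0.33, adjusted p = 5.51e-05). Among the next were the odorant binding protein gene Obp18a (4.32, SE 0.33, adjusted p = 0.000142), the endocytic receptor genes Cubn2 (4.17, SE 0.21, adjusted p = 2.59e-05, 18.0-fold) and Cubn (3.64, SE 0.23, adjusted p = 5.92e-05), lectin-33A (4.13, SE 0.47, adjusted p = 0.000813) and ltl (3.48, SE 0.39, adjusted p = 0.000813). The lowest were Sgs4, of a salivary glue protein (-6.48, SE 0.83, adjusted p = 0.00142, 89.3-fold lower), and the midgut protease gene Jon25Biii (-6.17, SE 1.04, adjusted p = 0.00482, 72.2-fold lower), followed among others by Muc11A (-5.80, adjusted p = 0.00736), Peritrophin-15a, of the gut lining (-5.74, adjusted p = 0.00141), and Fst (-5.62, adjusted p = 0.00494).

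Cardiac transcription factors were enriched in the vessel. Of 13 tested, 7 were higher in dorsal vessel, 1 was lower and 5 did not pass, with the same numbers adjusted over the list alone. After Hand, H15 was 10.8-fold higher (3.43, SE 0.18, adjusted p = 3.78e-05), pnr followed (1.18, SE 0.18, adjusted p = 0.00335), mid was at least 1.85-fold higher (adjusted p = 0.0288) and tin was 1.29-fold higher (0.37, SE 0.10, adjusted p = 0.0235). Lower in the vessel was svp, 4.56-fold (-2.19, SE 0.25, adjusted p = 0.000885). The list median was 0.37 (camera adjusted p = 0.00761; adjusted p = 0.463 with an estimated correlation), and without replicate 2 it was 0.43 and did not pass (camera adjusted p = 0.0700). Singly, tin missed the test without replicate 4 (adjusted p = 0.0833) or in the deposited value table (adjusted p = 0.0605), and mid without replicate 1, 2 or 3 (adjusted p = 0.0525, 0.113 and 0.112).

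Of 3 Hox genes tested, 1 was higher in dorsal vessel, abd-A (0.63, SE 0.10, adjusted p = 0.00417), 0 were lower and 2 did not pass, among them Antp (-0.28, adjusted p = 0.0648; 0.0446 without replicate 1); adjusted over the list alone, 1 was higher and 2 were lower. The median of the 3 was -0.28, and they were too few for a list test. Ubx and Abd-B were above detection on 0 arrays and were not tested. With the 2 dyes of each array fitted as separate channels and no pairing within the array, abd-A did not pass (adjusted p = 0.0616).

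All 7 genes of pericardial cells and nephrocytes that were tested were higher in dorsal vessel, 7 also when adjusted over the list alone, with 0 lower. Beside Cubn and Hand, Amnionless (0.99, adjusted p = 0.0083) and odd (at least 1.98-fold, adjusted p = 0.0129) belonged to them; Hand and odd are also members of the transcription factor list. Over its members the median was 0.99, or 1.99-fold (camera adjusted p = 4.40e-05; adjusted p = 0.438 with an estimated correlation). This median ran from 0.11 to 1.64 over the alternatives. Markers of the lymph gland and hemocytes were also enriched: of 15 tested, 7 were higher, 1 was lower and 7 did not pass, with the same numbers adjusted over the list alone. Among them were kn, a gene of the lymph gland signalling centre (at least 3.80-fold, adjusted p = 0.0044), Nplp2 (1.45, adjusted p = 0.00717), Pvr (0.92) and srp (0.71, adjusted p = 0.00371), and Hml did not differ (-0.00, adjusted p = 0.995). The 1 lower member was PPO2, which was higher in heart than in aorta. That list had a median of 0.71 (camera adjusted p = 0.00381; adjusted p = 0.463 with an estimated correlation). Singly, odd missed the test without replicate 3 or 4 (adjusted p = 0.0543 and 0.0506).

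Ion channel genes went both ways. Of 20 tested, 5 were higher in dorsal vessel, 5 were lower and 10 did not pass, with the same numbers adjusted over the list alone. The ryanodine receptor gene RyR (1.21, SE 0.17, adjusted p = 0.00205) and Ndae1 (at least 1.72-fold, adjusted p = 0.00923) were higher. The potassium channel genes Irk3 (at least 2.56-fold, adjusted p = 0.00623) and Ork1 (at least 1.37-fold, adjusted p = 0.0141) and the pump gene nrv3 (-1.16, adjusted p = 0.000662) were lower, and Ih did not pass (-0.27, adjusted p = 0.246). Across the list the median was 0.06 (camera adjusted p = 0.457). Ork1 missed the test without replicate 2 or 3 (adjusted p = 0.0701 and 0.0691). Of the 2 receptors of cardioactive peptides tested, MsR2 passed as lower, at least 2.54-fold, over all genes (adjusted p = 0.0376) and over the list alone. MsR2 had log2 ratios of -3.25 and -2.22 on replicates 1 and 2, where it lies in a block of spots found out of place, and -0.06 and 0.14 on replicates 3 and 4. It missed the test without replicate 3 (adjusted p = 0.0612), so no difference is read from it or from the median of the 2, -0.75.

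Sarcomere genes were more often lower than higher in the vessel, compared with whole larvae that contain the body wall muscle. Of 25 tested, 3 were higher in dorsal vessel, 12 were lower and 10 did not pass, with the same numbers adjusted over the list alone. Mf was higher (1.47, adjusted p = 0.00191), and Act57B (-2.12, SE 0.34, adjusted p = 0.00381), Mlp84B (-2.12, adjusted p = 0.000822), Mhc (-1.91, SE 0.32, adjusted p = 0.00475) and Actn (-1.05) were lower. As a group, the list had a median of -0.44 and the list did not pass (camera adjusted p = 0.230), but it did without replicate 4 (camera adjusted p = 0.0325). Mhc missed the test with print-tip loess (-0.70, adjusted p = 0.132), and Mf with the mean over oligonucleotides (0.46, adjusted p = 0.0794).

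Genes of the matrix, of adhesion and of signalling went both ways, and none of these lists passed camera. Of 15 matrix genes, 2 were higher, 1 was lower and 12 did not pass, with the same numbers adjusted over the list alone: Timp (2.49, SE 0.22, adjusted p = 0.000287) and trol (0.85) were higher and Tig was lower (-1.53, adjusted p = 9.07e-05), with a median of 0.13 (camera adjusted p = 0.238). Of 17 genes of adhesion and guidance, 6 were higher, 4 were lower and 7 did not pass (7 and 4 adjusted over the list alone). NetA (2.96, SE 0.16, adjusted p = 3.78e-05), mew (1.48, adjusted p = 0.00133) and parvin (0.77) were higher and fra was lower, at least 1.62-fold; parvin missed the test with print-tip loess (adjusted p = 0.0588) and in the deposited value table (adjusted p = 0.0708). The list median was 0.04 (camera adjusted p = 0.102), and without replicate 4 the list passed (camera adjusted p = 0.0223). Of 12 signalling genes, 3 were higher, 4 were lower and 5 did not pass, with the same numbers adjusted over the list alone: htl (at least 1.64-fold, adjusted p = 0.0071) and gbb (0.66) were higher and N (-1.98, SE 0.11, adjusted p = 4.70e-05) and Delta (at least 4.83-fold, adjusted p = 0.00327) were lower, and wg did not pass (-0.19, adjusted p = 0.182). That list had a median of -0.17 (camera adjusted p = 0.736; fry adjusted p = 0.0317, downward).

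The vessel was richer in genes of oxidative phosphorylation and poorer in genes of glycolysis than the whole larva. Of 30 genes of oxidative phosphorylation, 16 were higher, 0 were lower and 14 did not pass (19 higher adjusted over the list alone), with SdhD (0.98, adjusted p = 0.00309), COX4 (0.89, adjusted p = 0.00263) and COX5A (0.78, adjusted p = 0.00337) among them. The members had a median of 0.66 (camera adjusted p = 8.60e-07; adjusted p = 0.476 with an estimated correlation). Of 9 glycolysis genes, 0 were higher, 6 were lower and 3 did not pass (7 lower adjusted over the list alone), with Pgi (-1.60), Hex-A (-1.40) and Gapdh1 (-1.01) among them. Over its members the median was -0.98 (camera adjusted p = 0.00338; adjusted p = 0.476 with an estimated correlation). With print-tip loess the glycolysis list was at -0.46 and did not pass (camera adjusted p = 0.0678), and Gapdh1 was at -0.06 (adjusted p = 0.768). Of 9 genes of the tricarboxylic acid cycle, 2 were higher, 0 were lower and 7 did not pass, with the same numbers adjusted over the list alone and a median of 0.02 (camera adjusted p = 0.396). Idh3g was higher (0.90, adjusted p = 0.0199), though not without replicate 2, 3 or 4 (adjusted p = 0.0604, 0.0564 and 0.0692).

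Steroid genes of the ring gland were mostly lower in the dissected vessel. Of 9 tested, 1 was higher, 5 were lower and 3 did not pass, with the same numbers adjusted over the list alone. Lower were phtm (at least 3.81-fold, adjusted p = 5.62e-05), sro (-1.66) and spok (-1.27), and spo was higher (at least 1.40-fold, adjusted p = 0.00724). Across the list the median was -0.30 and the list did not pass in camera (adjusted p = 0.111), though it did in the rotation test (fry adjusted p = 0.000611), and camera found it at -1.46 with a stricter filter on dim genes (adjusted p = 0.0108).

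Genes of the other organs were depleted. Of 17 fat body genes, 13 were lower (14 adjusted over the list alone), 0 were higher and 4 did not pass, with Lsp2 42.1-fold lower (-5.39, SE 0.31, adjusted p = 4.76e-05) and Lsp1gamma at -5.35; the median was -1.32 (camera adjusted p = 2.31e-05; adjusted p = 0.344 with an estimated correlation). Of 13 genes of epidermis and cuticle, 11 were lower (11 adjusted over the list alone), 0 were higher and 2 did not pass, with Lcp1 at -5.16 (SE 0.63, adjusted p = 0.00113) and Lcp4 at -4.78; the median was -2.71, or 6.56-fold (camera adjusted p = 3.13e-05; adjusted p = 0.344 with an estimated correlation). Of 27 midgut genes, 19 were lower (23 adjusted over the list alone), 0 were higher and 8 did not pass, with Jon99Ciii at -5.90 and Jon66Ci at -4.91; the median was -2.81 (camera adjusted p = 2.31e-05; adjusted p = 0.476 with an estimated correlation). Of 14 genes of the salivary glands, 10 were lower (11 adjusted over the list alone), 0 were higher and 4 did not pass, with Sgs8 at -5.35 and Sgs3 at -4.64; the median was -2.43 (camera adjusted p = 0.000817; adjusted p = 0.476 with an estimated correlation). Among these calls, Lsp1beta (adjusted p = 0.0430) and FASN1 (0.0192) of the fat body and Sgs1 (0.0376) of the salivary glands, singled out after their values were seen, lie in the block of spots found out of place on replicates 1 and 2, so no difference is read from them. With that block left out the medians were -1.32 for the fat body and -4.64 for the salivary glands, and both lists passed camera. The size of these medians varied over the 22 alternatives, though the camera calls held at the preset correlation. They ran from -2.50 to -0.33 for fat body, -4.40 to -0.25 for epidermis, -3.66 to -0.58 for midgut and -4.76 to -0.27 for salivary glands.

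The remaining organs followed the same direction. All 3 genes of the Malpighian tubules tested were lower, 3 also over the list alone, with Uro at -4.62 (SE 0.88, adjusted p = 0.00792), and their median was -2.44. Of 14 genes of the testis and germ line, 10 were lower (12 adjusted over the list alone), 0 were higher and 4 did not pass, with Mst98Ca at -4.00 (adjusted p = 0.0131) and betaTub85D at -3.63 (adjusted p = 0.0188); the median was -1.58 (camera adjusted p = 0.00247; adjusted p = 0.552 with an estimated correlation). Of 6 tracheal genes, 4 were lower (5 adjusted over the list alone), 0 were higher and 2 did not pass, with vvl at least 4.48-fold lower and pio at -2.26; the median was -0.70 (camera adjusted p = 0.00379; adjusted p = 0.463 with an estimated correlation). Of 14 genes of imaginal discs, 9 were lower (11 adjusted over the list alone), 0 were higher and 5 did not pass, with en at least 3.61-fold and salm at least 3.40-fold lower; the median was -0.43 (camera adjusted p = 0.00449; adjusted p = 0.476 with an estimated correlation). Of 13 genes of the nervous system, 8 were lower (10 adjusted over the list alone), 1 was higher and 4 did not pass, with Syt1 at least 2.31-fold lower and elav at -0.72; the median was -0.34 (camera adjusted p = 0.0189; adjusted p = 0.476 with an estimated correlation), and the list missed the test without replicate 3 or 4 (camera adjusted p = 0.0983 and 0.0518). Mst98Ca and betaTub85D missed the test without replicate 2 (adjusted p = 0.0555 and 0.0633), 3 (0.0520 and 0.0695) or 4 (0.0515 and 0.0663).

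Ribosomal protein genes that passed were higher in the vessel, except RpS5b, singled out after its value was seen. Of 88 tested, 30 were higher, 1 was lower and 57 did not pass (39 and 1 adjusted over the list alone), with RpL6 (1.35, SE 0.15, adjusted p = 0.000671), RpL22 (1.17, adjusted p = 0.0048) and sta (1.02) among the higher. The list median was 0.45 (camera adjusted p = 4.28e-10; adjusted p = 0.476 with an estimated correlation), with replicate medians of 0.36, 0.26, 0.23 and 1.02, and the list missed fry (adjusted p = 0.0544). Of 12 cell cycle genes, 0 were higher, 1 was lower, polo (-0.64), and 11 did not pass, with the same numbers adjusted over the list alone and a median of -0.39 (camera adjusted p = 0.426). The call on polo was lost without replicate 2, 3 or 4 (adjusted p = 0.0712, 0.0510 and 0.0644).

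**Figure D3:**
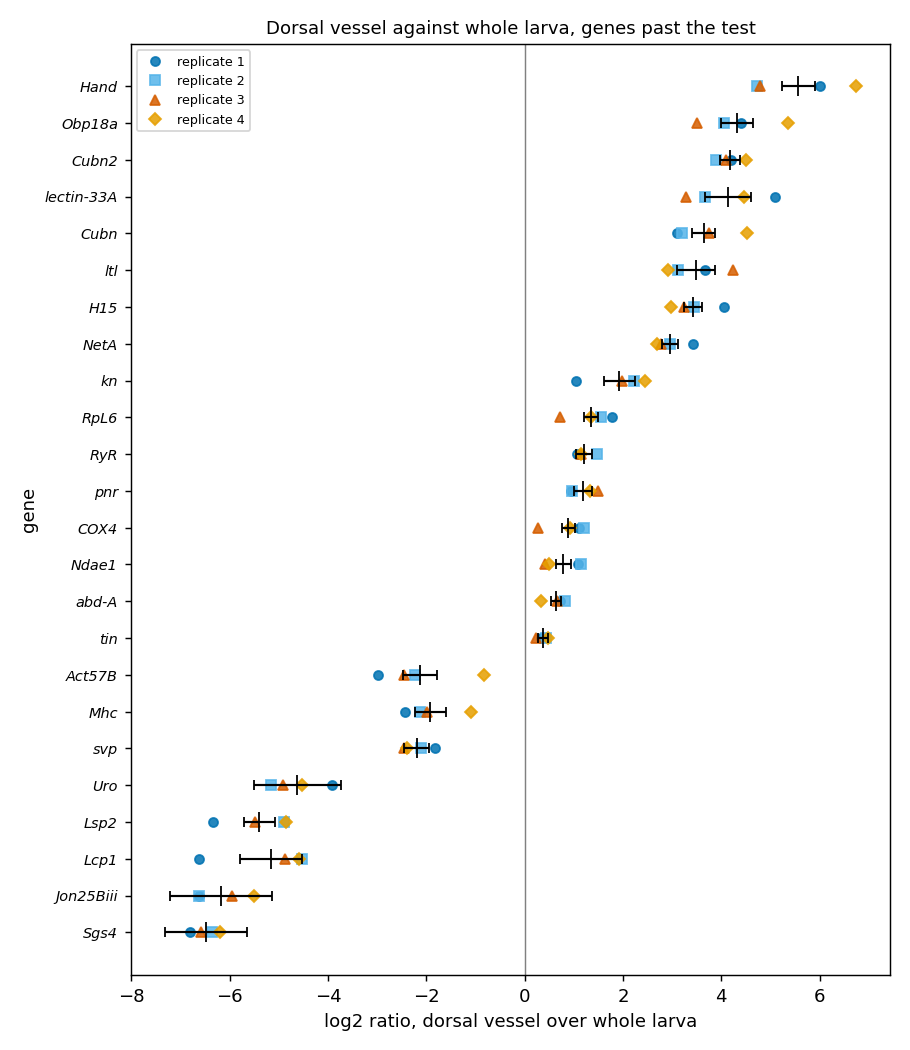
Genes that differed between dorsal vessel and whole larva. Each point is the log2 ratio of dorsal vessel over whole larva on an array, with replicates shown by colour (n = 4 arrays); the black tick is the fitted log2 ratio and the bar its standard error. Positive values mean higher in dorsal vessel.

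The count of 2480 fell to 2109, 1368, 1310 and 1401 without replicate 1, 2, 3 or 4. The balance of higher and lower genes also moved with the processing. It was 845 and 1005 with median centring, 852 and 923 with an offset of 50 RFU and 831 and 1584 with no background correction. With median centring, Actn, Gapdh1, Ndae1, elav, gbb, mid, polo and tin missed the test (adjusted p = 0.0515 to 0.264). With an offset of 50 RFU, chosen after the data were seen, Nplp2, RpL22, trol, odd, Ndae1, mid, DptA, Mst98Ca, betaTub85D and Gapdh1 missed it (adjusted p = 0.0550 to 0.142). With no background correction spo and tin missed it (adjusted p = 0.0560 and 0.0706), and Idh3g and mid did with no dye effect (adjusted p = 0.0663 and 0.0505). The nervous system list missed camera with a stricter filter (adjusted p = 0.107). Whole larvae contain the dorsal vessel, so its genes are present on both sides of this comparison. No array separated the amount of an organ in the dissected tissue from regulation within it.

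The pair of comparisons shared genes in most directions. Of 5261 genes tested in both, 93 passed in both. That number was 33, 23, 65 and 45 without replicate 1, 2, 3 or 4 of heart against aorta, 52, 46, 36 and 137 without those of dorsal vessel against whole larva, and 3 or 4 with each comparison fitted on its own arrays, with or without a dye effect. The numbers by direction below hold for the joint fit alone. Genes higher in heart and in dorsal vessel numbered 38 (19.6 expected by chance, Fisher p = 2.12e-05), among them abd-A, wun2, CAH7, sosie, COX4 and COX5A. Genes higher in heart and lower in dorsal vessel numbered 35 (21.6 expected, Fisher p = 0.00213), among them PPO2, Agps and Tig. Genes higher in aorta and in dorsal vessel numbered 15 (7.63 expected, Fisher p = 0.00735), among them tin, NetA, RpL6, sand and Lapsyn, and genes higher in aorta and lower in dorsal vessel numbered 5 (8.38 expected, Fisher p = 0.245). Across all 5261 genes the log2 ratios of the comparisons had a Spearman rho of -0.106. The comparisons shared no RNA, but genes are not independent of each other and the joint estimate of a gene's spread favours coincidence in any direction.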

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

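No test in this part was chosen after its result was seen: a replicate far from the other 3 was sought with Dixon's test in each group of 4 values named in the text, and signals in data not reported on were sought among the control spots. Of 208 groups, 10 had such a replicate, where 10.4 would be found by chance. The arrays were not left out for it, and no biological explanation was tested, because the pools carry no label beyond the replicate number.

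For heart over aorta, Agps had a log2 ratio of 1.05 on replicate 3 (2.34 to 2.53 on the others), tin -0.73 on replicate 1 (-0.47 to -0.43), Ndae1 -0.0257 on replicate 4 (0.42 to 0.49) and Zasp66 0.42 on replicate 1 (0.78 to 0.84). The median of the lymph gland and hemocyte list was 1.26 on replicate 3 (0.51 to 0.61).

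For dorsal vessel over whole larva, N had a log2 ratio of -2.21 on replicate 2 (-1.93 to -1.89 on the others). On replicate 1, Delta stood at -1.37 (-2.63 to -2.45), salm at -1.08 (-2.04 to -1.97) and Lcp1 at -6.63 (-4.87 to -4.53). The median of the ribosomal protein list was 1.02 on replicate 4 (0.23 to 0.36).

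Among 11 external control oligonucleotides, which match no fly gene, 8 lay above the detection level in all 16 channels and 1 in none. The control spots were not used in the analysis.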

How the results depend on the processing

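Of the alternatives, 4 were chosen after seeing the data: a literal normexp offset of 50 RFU, a separate dye effect for each comparison, heart against aorta without replicates 1 and 3, and a displaced block of spots left out. A block by slide or scan date was not run, because the files hold no such field.

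The number of genes that differed between heart and aorta, 152, changed with many choices. It was 97 with median centring (88 higher in heart, 9 in aorta), 70 with no filter on dim genes, 256 with a stricter one, 273 with array weights, 60 with an offset of 50 RFU and 457 with a separate dye effect (230 and 227). On the 4 arrays of the comparison alone it was 8 with a dye effect and 11 without, and leaving out 1 array gave 36 to 119, where fewer arrays carry the estimate. Without replicates 1 and 3 it was 24. The cause was not tested for the others. The dye effects of the 2 sets of arrays correlated at rho = 0.0598, so the shared dye effect of the main fit was not borne out. The number of genes stayed between 132 and 178 with no background correction, offset 0, print-tip loess, Aquantile, marked spots kept, no dye effect or the mean over oligonucleotides. With no pairing of the 2 channels in a block per array, 145 genes passed, and 188 did in the deposited value table. Of the 152 genes, 94 were among those 145 and 125 were among those 188. For dorsal vessel against whole larva the 2480 genes became 1310 to 2109 with 1 array left out and 2332 with no pairing.

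Over all alternatives, values of named genes past the test stayed past it 435 times and missed it 117 times for heart against aorta. They did so 1832 and 68 times for dorsal vessel against whole larva. List medians did so 209 and 40 times and 301 and 7 times. Calls on genes not named were not followed in this way. PPO2 passed in all 23 for heart over aorta, at 1.86 to 2.79. So did the sarcomere (0.17 to 0.77), matrix (0.11 to 0.72), hemocyte (0.21 to 1.02), ribosomal protein (-0.58 to -0.06) and cell cycle lists (-1.07 to -0.12) at the preset correlation.

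Of the lists that passed, 11 for heart against aorta became 0 with an estimated correlation, 2 by fry and 7 to 11 with 1 array left out; 14 for dorsal vessel against whole larva became 0 with an estimated correlation. With no pairing, 10 and 15 lists passed.

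The 93 genes shared by the comparisons became 60 with median centring, 41 with no filter, 144 with a stricter one, 162 with array weights, 33 with an offset of 50 RFU, 265 with a separate dye effect, 3 and 4 on the arrays of each comparison alone with and without a dye effect, 16 without replicates 1 and 3, 23 to 137 with 1 array left out and 77 with no pairing. The cause was not tested.

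Among the named genes followed and the lists, no value past the test changed direction. Of the named genes and lists not past it, these did by more than the spread of replicates or past the test. The cause was not tested. For heart over aorta, Hand was 0.20, the fat body list 0.0812 and the nervous system list 0.0961 with median centring, which moved the median of all genes to 0.16; Ih was -0.32 with marked spots kept; H15 was 0.0518 in the deposited value table; the testis list ranged from -0.818 to 0.714 with 1 array left out; and the heat shock list was 0.0377 without replicates 1 and 3. For dorsal vessel over whole larva, the tricarboxylic acid cycle list was -0.0957 with offset 0 and -0.0916 in the deposited value table, which moved the median of all genes to -0.13 and -0.16 (-0.17 with no background correction). The signalling list was 0.0363 with no filter, 0.206 with a stricter one, and ranged from -0.235 to 0.0198 with 1 array left out.

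Other values not past the test also took both signs, by less than the spread of replicates. For heart over aorta these were svp (-0.42 to 0.11), Act57B (-0.65 to 0.19), betaTub85D (-1.05 to 1.05), Scr (-0.02 to 0.17) and the lists of midgut (-1.92 to 0.67), immune peptides (-0.67 to 0.55), salivary glands (-0.03 to 1.42), cardiac transcription factors (-0.41 to 0.05), adhesion (-0.09 to 0.25), signalling (-0.02 to 0.23), nephrocytes (-0.00 to 0.39), ring gland (-0.01 to 0.21) and imaginal discs (-0.20 to 0.07). For dorsal vessel over whole larva they were Hml (-0.17 to 0.20) and the lists of heat shock (-0.51 to 0.26), immune peptides (-0.75 to 0.08), ion channels (-0.02 to 0.13) and adhesion (-0.02 to 0.21).

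Low signal limits what was seen: 23.5 to 48.1% of spots per channel lay at or below local background, and changes in dim genes are understated. The files hold no column for saturation.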

Other observations

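Stress and immune genes have not been described above. Between heart and aorta, 15 heat shock and stress genes were tested and 15 did not pass in limma, among them Hsp27 (-0.88, adjusted p = 0.112), with a median of -0.02 (camera adjusted p = 0.458). Of 8 immune peptide genes tested, 8 did not pass, and over either list alone 0 did, with replicate medians of 1.79, 0.21, -1.57 and -0.55 (overall -0.14, camera adjusted p = 0.458), and without replicate 1 that list passed (camera adjusted p = 0.0345). Between dorsal vessel and whole larva, 2 of 16 stress genes were higher and 2 were lower, with GstD1 higher (1.30, adjusted p = 0.00814) and TotA lower (-5.18) and 12 not past the test, with the same numbers adjusted over the list alone; the median was 0.10 against a mean of -0.27 (camera adjusted p = 0.750). Of 14 immune genes, 2 were higher, 8 did not pass and 4 were lower, with the same numbers adjusted over the list alone, among them DptA (at least 2.44-fold) and PGRP-SB1 (at least 2.15-fold), with a median of -0.37 (camera adjusted p = 0.460); AttD, among the 4, lies in the block of spots found out of place on replicates 1 and 2.

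Genes of the midgut, salivary glands and testis shifted in opposite directions on replicates 1 and 3 of heart against aorta. Of the tests on this pattern, that of other organs was set before its result was seen, and those of exchanged labels and of whole larvae were chosen after the pattern was seen. The hemocyte list went against an exchange of heart and aorta on 1 array, since its lower median on these replicates was 0.578 with the same sign as elsewhere. That list was called in a fit that included both replicates, so the check is weak. RNA of other organs in the heart pool of replicate 1 and the aorta pool of replicate 3 remains a candidate explanation: across 4895 genes outside the lists, the difference of these replicates followed whole larva over dorsal vessel at rho = 0.532, against 0.198 for replicates 2 and 4. Both of these pools were labelled with Cy5, so a cause tied to that dye was not told apart from this explanation. Midgut medians lay on the Cy5 side of all 4 heart and aorta arrays, but testis medians on that of replicates 1 and 3 only. Against whole larva, midgut medians were similar in both dye orientations (-1.99, -2.74, -2.84 and -2.58 on replicates 1 to 4). Carry-over of RNA of whole larvae was argued against, since 22 genes of fat body and epidermis shifted by a median of -0.150 where midgut genes shifted by 3.53.

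On dorsal vessel against whole larva, Sgs1 and Lsp1beta, chosen after their values were seen, had log2 ratios of 0.32, 0.09, -4.99 and -4.15 and of 0.04, 0.13, -5.40 and -4.88 on replicates 1 to 4. The test of dye bias was set before its result, and those of stage and of the spot grid were chosen after. By the rule set, a rho of 0.0598 between the dye effects of the separate sets of arrays went against dye bias. Both sets held arrays with a displaced block of spots, described below. Replicates 1 and 3 of heart against aorta also held the shifts toward Cy5 described above. The correlation therefore does not decide on dye bias of single oligonucleotides. A difference of stage as the cause was argued against by the other glue protein genes: between pools 1 and 2 and pools 3 and 4, Sgs1 and Lsp1beta differed by 4.78 and 5.22, Sgs3, Sgs4, Sgs5 and Sgs7 by -0.67, -0.20, 0.67 and -1.11, and Sgs8 by -2.31, in the opposite direction. That difference of Sgs8 was left unexplained. It lay on the Cy5 side, as did the mean log2 Cy5 over Cy3 of Sgs8 on the heart and aorta arrays, 2.65. The difference of Sgs5 lay on the Cy3 side, though its mean on the heart and aorta arrays was 1.66. A cause tied to the dye was not tested for these genes singly. A spot grid displaced by 1 column in the block of 656 spots that holds both is likely: moved by 1 column, the block correlated with the other arrays at rho = 0.600 and 0.708 on replicates 1 and 2, and in place at 0.0209 and 0.0589. The block was displaced on replicate 3 of heart against aorta too, and leaving it out on these 3 arrays kept 150 of the 152 genes and 2441 of the 2480, but 8 in place of 11 lists for heart against aorta, since the ion channel, tricarboxylic acid cycle and epidermis lists no longer passed (camera adjusted p = 0.0722, 0.0512 and 0.0512).

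The negative log2 ratios of cell cycle genes may come from the lymph gland, which lies beside the anterior aorta. Their list passed camera at the preset correlation, but not with an estimated one (camera adjusted p = 0.582) or by fry. The test of progenitors was set before its result, and that of imaginal discs was chosen after. Markers of lymph gland progenitors and of its signalling centre had a median log2 ratio of -0.602 (4 of 8 were tested): Tep4 -1.23 (adjusted p = 0.0631), et -0.98 (adjusted p = 0.0842), dome -0.23 and kn -0.05, none past the test. The imaginal disc list had a median of -0.0573, but only 5 of its 19 genes on the arrays were tested. Ratios of dim genes are understated, so this median does not decide on imaginal disc cells. The hemocyte list was higher in heart, so the idea would need progenitors in the aorta pools and mature hemocytes in the heart pools, and no array here separates these cells.

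Whether chance could yield the counts was asked by turning the sign of arrays. For heart against aorta the real signs gave the highest count, 152, in 1 of 8 splits, and the highest other was 2; for dorsal vessel against whole larva 2480 in 1 of 8, and the highest other was 0. For lists, 2 of 8 splits gave as many as 11 (highest other 12) and 2 of 8 as many as 14 (highest other 14). Every turned split called lists, 5 to 12 for heart against aorta and 2 to 14 for dorsal vessel against whole larva. The counts of lists therefore do not set the real signs apart. With 8 splits none of the counts of genes or lists can reach a share below 0.05. For genes shared by the comparisons, 1 of 64 pairs of splits gave as many as 93 and the highest other was 2. No turned split called over 2 genes in its own comparison, so no pair with a turned split could have shared more, and the pairs add nothing to the 8 splits of each comparison.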
